A study of Nicotiana benthamiana with 9 samples.

How the data were processed

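Leaves of Nicotiana benthamiana, a relative of tobacco widely used for transient expression, were sampled in 3 groups of 3 libraries each. One group expressed the P19 silencing suppressor alone, and the other 2 expressed P19 together with the editing factor dPPRe-rpl2 from the vector pGWB2 or pMDC32. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into directional libraries by dUTP marking of the other strand. The labels give 2 days post infiltration (dpi) for replicate 1 of every group and 3 dpi for replicates 2 and 3, whereas the series text gives 3 dpi for all, so the labelled day and the replicate number cannot be told apart.

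The deposited values are raw counts of reads per gene, made by the authors and not normalized. The submitters' processing notes name FastQC 0.12.1, Trim Galore 0.6.10, HISAT2 2.2.1, featureCounts 2.0.1 and DESeq2 1.42.0. The genome build, the strand setting and the treatment of multiply mapped or overlapping reads are not given in the sources used here. The table holds 106 rows, of which 105 are plastid genes (80 protein-coding, 21 tRNA and 4 rRNA genes) and 1 is the editor transgene. Nuclear and mitochondrial genes were not analysed here, and neither were RNA editing levels, which counts do not carry. Because only plastid rows and the transgene row entered the totals, every fold change of a plastid gene is relative mainly to the other plastid genes. The transgene took at most 1.06% of counts (pMDC32 replicate 2). A change of all plastid RNA together would not show in plastid genes, and it would shift the transgene values, which are relative to the same counts. Libraries held 32457135 to 44392760 counted reads. The sequencing lane was read from the column names: lanes 8, 4 and 4 for P19 replicates 1 to 3, lane 4 for all pGWB2 libraries, and lanes 8, 8 and 5 for the pMDC32 libraries.

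Counting of some rows was uncertain. The rps12 row spans 70359 nt (71935 to 142293) with 37 other rows inside it, 9 of them on its strand, and took 8.76% to 12.3% of counts per library. The trnK row contains matK and exceeded it in all 9 libraries, by 1.42 to 1.56 times. Apart from overlaps with rps12, 10 rows overlap another row on the same strand. Genes of the inverted repeat are listed as a single copy, and reads of the repeat may have been split or discarded.

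Groups were compared with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test on the deposited counts, with TMM normalization, the filterByExpr filter (passed by all 106 rows) and two-sided p-values adjusted by the Benjamini-Hochberg method over all rows, with a threshold of 0.05. All 9 libraries entered 1 fit for the comparisons of vectors, the 6 editor libraries were set against P19 in another, and labelled days were compared with the group as covariate. The series text calls the libraries biological replicates. Gene lists of plastid functions were tested by camera in limma 3.58.1 with a preset correlation of 0.01, beside camera with an estimated correlation and fry. Of 16 lists, 15 had measured members, and the list of mitochondrial genes had 0. Shares of counts were compared by exact permutation tests, for which 3 against 3 libraries cannot give a p below 0.1 and 6 against 3 cannot give one below 0.0119. CPM are counts scaled to a common library size (CPM of edgeR) with TMM factors. Intervals at 95% on counts and floors of 3 counts cover counting error only.

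The tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined, except where an alternative is said to have been added. The rule names rpl2 with its neighbours rpl23, rps19 and rpl22, then rbcL, psbA, psaA, ndhB, rpoA, accD and clpP (listed as clpP1), and for each comparison the genes past the threshold or, where fewer than 10 pass, those with the smallest p up to 10, with 2 to 4 members of each list. Alternatives were other normalizations, no filter, DESeq2 1.42.0, limma-voom, leaving out rRNA and tRNA rows, each library in turn, the replicate number as a block, the labelled day as covariate, the 3 dpi libraries alone, and fits of only the groups compared. No pair of replicates agreed within sampling noise (chi-square per degree of freedom 1359 to 21246), so no library was taken for a second deposit of another, which does not show that they came from separate plants. On data simulated from these libraries, with 20 of 105 genes changed in 40 runs, the test of pGWB2 against P19 recovered 15.4% of changes of 1.5-fold, 86.4% of 2-fold and 99.6% of 3-fold. For pMDC32 against P19 the shares were 17.1%, 84.4% and 99.5%, and for both vectors against P19 they were 35.9%, 94.6% and 99.5%. These simulations drew genes independently, gave a gene the same dispersion in all groups and changed as many genes up as down. The shares may therefore not hold for the real libraries.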

Results

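Plastid transcripts were counted in leaves that expressed dPPRe-rpl2, a designed RNA editing factor built on pentatricopeptide repeats (PPR), which are RNA-binding protein modules. Its name points to rpl2, the plastid gene of a large ribosomal subunit protein. The factor was expressed with P19, a viral suppressor of RNA silencing, from pGWB2 (3 libraries) or pMDC32 (3 libraries), and leaves with P19 alone (3 libraries) were the control. Counted reads per library ran from 32457135 to 44392760. The psbA transcript, for the D1 protein of photosystem II, took 53.7% ± 7.0 of counts in P19 leaves, 48.5% ± 1.43 with pGWB2 and 47.1% ± 2.92 with pMDC32 (SD, n = 3 each).

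The editor transcript was abundant in every editor library and nearly absent from P19 leaves. It reached 3241 ± 1750 CPM with pGWB2 and 6157 ± 3538 CPM with pMDC32 (SD, n = 3 each). In P19 libraries 0, 11 and 4 reads were counted, and the 0 of replicate 1 allows up to 0.116 CPM. Against P19 the transgene rose by 14.38 on the log2 scale with pGWB2 (SE 1.04, adjusted p = 1.7e-05) and by 15.31 with pMDC32 (SE 1.07, adjusted p = 1.2e-05), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. It was higher in 6 of 6 editor libraries than in every P19 library.

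**Figure D1:**
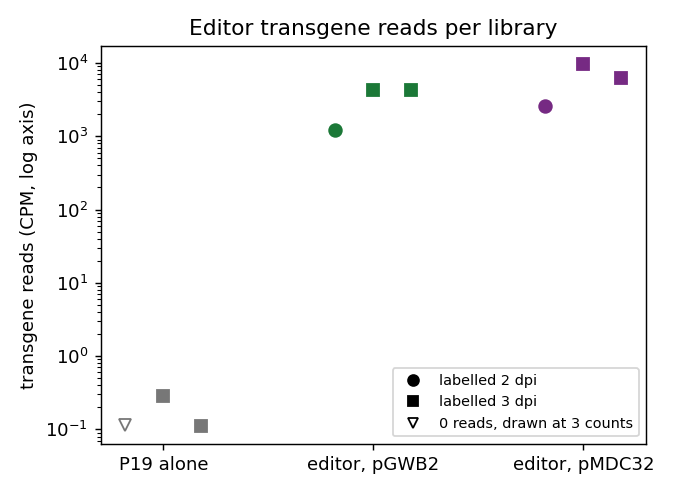
Editor transgene reads in CPM (log axis) for each of the 9 libraries, with circles for libraries labelled 2 dpi and squares for 3 dpi. The 6 editor libraries lie between 1221 and 9675 CPM, and the P19 library with 0 reads is drawn as an open triangle at its limit of 3 counts.

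The comparison of pGWB2 with P19 asked whether the editor changed plastid transcript levels. No plastid gene passed the test. The rpl2 transcript (154104 to 155605, plus strand, on a plastid sequence whose build is not given in the sources used here) stood at 1067 ± 82.2 CPM with pGWB2 and 957 ± 276 CPM in P19 (SD, n = 3 each), a log2 difference of 0.16 (SE 0.26). Its neighbours rpl23, rps19 and rpl22, also for ribosomal proteins, had log2 differences of 0.17 (SE 0.23), 0.29 (SE 0.33) and 0.25 (SE 0.35). The smallest p-values belonged to rps12 (-0.23), trnT (-0.35), atpB of the ATP synthase (0.41), psbM of photosystem II (-0.52), rps16 (-0.55), trnG (-0.55), rpl33 (0.29), rrn23 (-0.68) and trnN (-0.35). By edgeR's quasi-likelihood test 0 of 105 plastid genes had a Benjamini-Hochberg adjusted p under 0.05 (smallest 0.55), 6 had an unadjusted p under 0.05 where chance gives 5.25, DESeq2 called 1 (rpl33) and limma-voom 0. The 95% interval lay within 2-fold for 90 of the 105 genes. Without P19 replicate 1 the log2 differences were -0.031 for rpl2, -0.028 for rpl23, -0.010 for rps19, -0.078 for rpl22, -0.25 for psbM and -0.20 for rrn23.

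Of the 15 gene lists, 4 passed camera with the preset correlation in this comparison. The ATP synthase genes (adjusted p = 0.0205) and the rpl23-rpl2 cluster (adjusted p = 0.0205) ranked above the other genes, and the rRNAs (adjusted p = 0.0265) and tRNAs (adjusted p = 0.0205) below them. With an estimated correlation their adjusted p-values were 0.367, 0.776, 0.367 and 0.367, so that 0 lists passed, and fry called 0. Ribosomal RNA had been depleted from the libraries, so values of rRNA rows may reflect what depletion left and not transcript levels. P19 replicate 1 stood apart from the other libraries, with psbA at 61.1% of counts against 44.0% to 52.6% elsewhere, and without it 1 list passed, the ATP synthase.

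With pMDC32 as well, no plastid gene passed the test. The rpl2 log2 difference from P19 was 0.29 (SE 0.26), with 1166 ± 328 CPM for pMDC32 (SD, n = 3), and those of rpl23, rps19 and rpl22 were 0.19 (SE 0.23), 0.45 (SE 0.33) and 0.39 (SE 0.35). The smallest p belonged to petL, for a small subunit of the cytochrome b6f complex (68008 to 68103, plus strand), which stood at 399 ± 21.9 CPM with pMDC32 and 709 ± 268 CPM in P19 (SD, n = 3 each), a log2 difference of -0.83 (SE 0.24). It was followed by trnN (-0.51), trnfM (-0.60), rpl33 (0.33), psbM (-0.51), trnK (0.42), psbA (-0.44), rps12 (-0.20) and rps7 (0.43). By edgeR's quasi-likelihood test 0 of 105 plastid genes had a Benjamini-Hochberg adjusted p under 0.05 (smallest 0.336, petL), and 6 had an unadjusted p under 0.05. DESeq2 called 1 (rpl33) and limma-voom 0. Without P19 replicate 1, which had 1014 CPM of petL against 510 and 604 in the other P19 libraries, the log2 differences were -0.41 for petL, -0.072 for psbA, -0.19 for psbM, -0.12 for rps12, 0.13 for rpl2, 0.033 for rpl23, 0.19 for rps19 and 0.10 for rpl22. Adjusted over the list alone, 1 of the 6 cytochrome b6f genes passed (petL, adjusted p = 0.038 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), against 0 over all genes.

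The lists that passed camera with the preset correlation numbered 4 for pMDC32. The rpl23-rpl2 cluster (adjusted p = 0.00273), the ATP synthase (adjusted p = 0.046) and the large ribosomal subunit proteins (adjusted p = 0.046) ranked higher than the other genes, and the tRNAs (adjusted p = 0.0361) lower. With an estimated correlation the adjusted p-values were 0.72, 0.634, 0.702 and 0.634, and 0 lists passed by that test or by fry. Without P19 replicate 1, 0 lists passed.

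Setting the vectors against each other asked whether the choice of vector mattered. The transgene was 0.93 higher on the log2 scale with pMDC32 (SE 0.58, 95% interval -0.37 to 2.23, adjusted p = 0.998 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). With the labelled day as covariate it was 0.97 (SE 0.24, 95% interval 0.41 to 1.52, unadjusted p = 0.00369 and adjusted p = 0.391 by the same test), which does not pass over all rows. The pMDC32 library held more than the pGWB2 library at each replicate number (2599 against 1221, 9675 against 4266 and 6197 against 4236 CPM). Among plastid genes the smallest p belonged to petL at -0.55 (SE 0.24), and trnfM (-0.40), rrn4.5 (-0.71), psbT (-0.13), rrn16 (0.40), psbB (-0.13), rrn23 (0.31), trnH (0.15) and rps16 (0.22) came next, with rpl2 at 0.13 (SE 0.26). By edgeR's quasi-likelihood test 0 of 105 plastid genes had a Benjamini-Hochberg adjusted p under 0.05, 1 had an unadjusted p under 0.05 where chance gives 5.25, and DESeq2 and limma-voom called 0. All 9 libraries set the spread of this fit, so the P19 libraries, which are outside the comparison, entered these SE values. In a fit of the 2 editor groups alone petL passed (log2 difference -0.56, SE 0.12, adjusted p = 0.0331 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of the 15 lists 0 passed camera.

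The 6 editor libraries together against P19 gave a median SE of 0.163 over plastid genes, against 0.202 for either vector alone. The rpl2 log2 difference was 0.22 (SE 0.21, 95% interval -0.25 to 0.69, adjusted p = 0.489 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and those of rpl23, rps19 and rpl22 were 0.18, 0.38 and 0.32. Transcripts of rbcL, the large subunit of Rubisco, differed by 0.14 (SE 0.06), psbA by -0.40 (SE 0.16), psaA of photosystem I by 0.27 (SE 0.18), ndhB of the NDH complex by 0.21 (SE 0.14), rpoA of the plastid RNA polymerase by 0.05 (SE 0.12), accD of acetyl-CoA carboxylase by -0.08 (SE 0.14) and the protease subunit clpP1 by -0.03 (SE 0.11). The smallest p-values belonged to trnN (-0.43), psbM (-0.52), rps12 (-0.21), rpl33 (0.31), trnT (-0.32), atpB (0.37), rps7 (0.42), psbA and trnG (-0.47). By edgeR's quasi-likelihood test 0 of 105 plastid genes had a Benjamini-Hochberg adjusted p under 0.05 (smallest 0.264), 16 had an unadjusted p under 0.05, DESeq2 called 3 (trnT, rpl33 and rbcL) and limma-voom 0. For the 16, chance gives 5.25 on average, but another split of the 9 libraries reached 36. The interval lay within 2-fold for 99 of the 105 genes. Without P19 replicate 1 the log2 differences were 0.052 for rpl2, 0.0030 for rpl23, 0.092 for rps19, 0.015 for rpl22, -0.061 for psbA, 0.15 for psaA, 0.33 for ndhB and -0.22 for psbM.

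**Figure D2:**
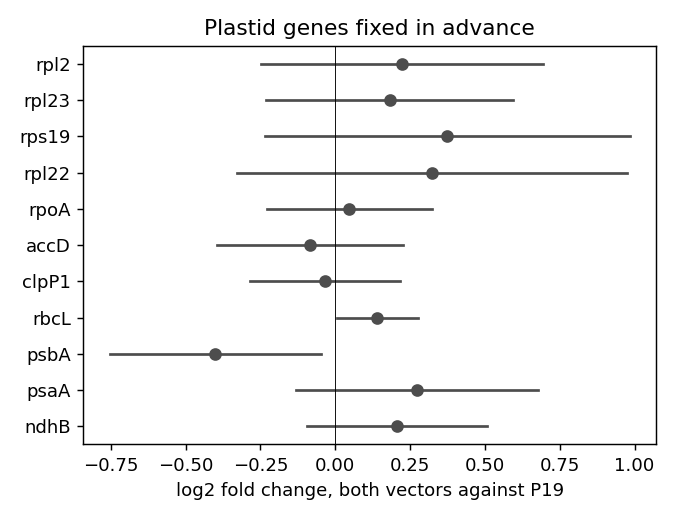
Log2 fold change of the 6 editor libraries against the 3 P19 libraries for the plastid genes named in advance, as points with 95% intervals as lines. The interval of rpl2 runs from -0.25 to 0.69, and no gene shown passed the test after adjustment.

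Gene groups were described over both vectors. The ATP synthase had 6 of 6 members above P19 (0.00 to 0.37), the rpl23-rpl2 cluster 12 of 12 (0.05 to 0.38) and the tRNAs 17 of 21 below it (-0.60 to 0.38). These 3 lists passed camera with the preset correlation (adjusted p = 0.028, 0.00704 and 0.0278), and none did with an estimated correlation (adjusted p = 0.413, 0.794 and 0.413), by fry, or by single members, since 0 genes of any list passed adjusted over the list alone. The cluster's genes had an estimated correlation of 0.91, and without P19 replicate 1 the ATP synthase was the 1 list that passed. Directions of many groups turned without that library, a setting chosen after seeing the data. Below P19 lay 13 of 15 photosystem II genes (4 of 15 without it), 5 of 6 cytochrome b6f genes (1 of 6), 4 of 4 rRNAs (4 of 4) and 7 of 12 inverted repeat genes (7 of 12). Above P19 lay 7 of 9 large and 8 of 12 small ribosomal subunit genes (6 of 9 and 6 of 12 without it), 4 of 7 photosystem I genes (7 of 7) and 3 of 4 RNA polymerase genes (0 of 4). Of the cluster 6 of 12 genes then lay above P19, of the ATP synthase 6 of 6, and of the tRNAs 15 of 21 below it. The NDH complex (4 of 11 above), genes transcribed by the nuclear-encoded polymerase (3 of 7), transcripts edited in tobacco (7 of 16) and other plastid genes (5 of 10) were ranked up by camera while their medians were -0.12, -0.03, -0.07 and -0.00. The first 3 of these had 7 of 11, 2 of 7 and 10 of 16 above without P19 replicate 1. Apart from the cluster, the ATP synthase and the tRNAs, no list passed.

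**Figure D3:**
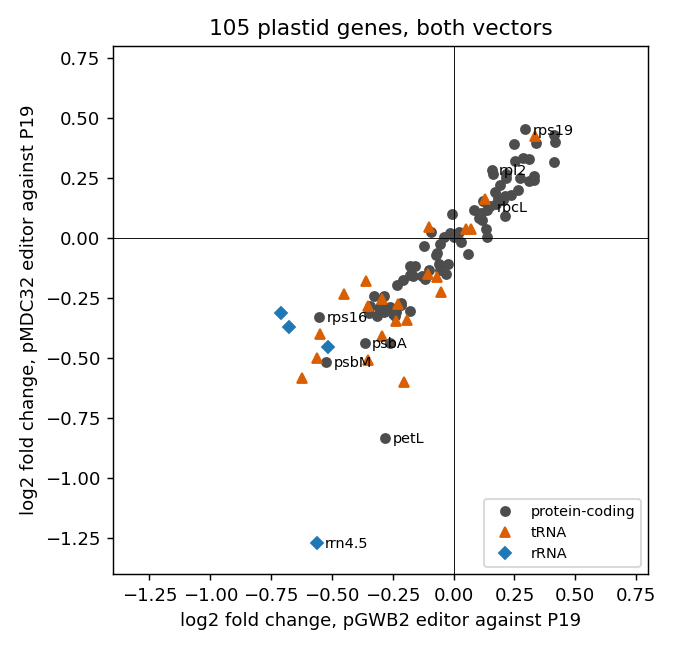
Log2 fold change against P19 of the 105 plastid genes with pGWB2 (horizontal axis) and pMDC32 (vertical axis), with gene classes by symbol. Both axes share the same 3 P19 libraries, and 97 of the 105 genes have the same sign on both.

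Fold changes of the vectors had the same sign in 97 of 105 genes (92.4%, where unchanged groups against the same controls gave 66.5% in 500 simulations). Their correlation across genes, which are not independent replicates, was 0.905 against 0.495 simulated, and their covariance was 0.0744 against 0.0335, a difference of 0.0409. The correlation without P19 replicate 1 was 0.891 against 0.595 simulated and the covariance 0.0649 against 0.0249. The simulations drew genes independently and gave a gene the same dispersion in all groups. Protein-coding genes of replicate 1 deviated with an SD of 0.736 in P19, 0.189 with pGWB2 and 0.21 with pMDC32. As the excess remained without P19 replicate 1, the spread of that library alone does not account for it. Simulated values may still understate what shared controls add, as genes were drawn independently, and the excess does not show an effect of the editor. No gene was called in either comparison, so independent lists would share 0, and part of the excess may come from the shared controls, which were too few to split.

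No share of counts by RNA class passed its test after adjustment. The psbA share with the editor minus that in P19 was -5.85 percentage points (exact permutation test, two-sided, p = 0.0595, adjusted 0.238 over 4 classes), and -2.12 without P19 replicate 1. The tRNA share was 2.22% ± 0.339 against 1.83% ± 0.63, and the rRNA share 0.059% ± 0.0152 against 0.0702% ± 0.0162 (SD, n = 6 and n = 3, exact permutation p = 0.226 and 0.31). These differences were 0.0617 and -0.00186 percentage points without P19 replicate 1. The tRNA share was higher with the editor although 17 of 21 tRNA rows lay below P19 after TMM normalization. It includes the trnK row, which contains matK, so it is not a measure of tRNAs alone. Every pGWB2 library had a lower rRNA share than every P19 library (0.0516% ± 0.0117 against 0.0702% ± 0.0162, SD, n = 3 each, exact permutation p = 0.1, the smallest possible, adjusted 0.4), a difference of -0.0187 points that was -0.00931 without P19 replicate 1. As the libraries were depleted of ribosomal RNA, these shares may reflect what depletion left.

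The labelled day divided the editor transcript, while no plastid gene passed the planned test over all 9 libraries. Across plastid genes, deviations of replicate 1 from replicates 2 and 3 correlated at 0.719 between the 2 editor groups. With those of P19 replicate 1 they correlated at 0.088 (pGWB2) and -0.197 (pMDC32), so a difference by day within the editor groups is not excluded. The transgene was lower in libraries labelled 2 dpi by 1.75 on the log2 scale than in those labelled 3 dpi (-1.75, SE 0.27, adjusted p = 0.016 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The mean of the 3 dpi libraries was 3.48 times the 2 dpi library with pGWB2 and 3.05 times with pMDC32. Smallest p-values among plastid genes belonged to trnA (-0.64), trnR (-0.73), psbA (0.37), trnV (-0.45), atpI (0.31), rps16 (-0.41), trnI (-0.44), petB (0.30) and rpoC2 (-0.58). By edgeR's quasi-likelihood test 0 of 105 plastid genes had a Benjamini-Hochberg adjusted p under 0.05 (smallest 0.209), 12 had an unadjusted p under 0.05, DESeq2 called 2 (trnR and trnA) and limma-voom 0. Each group has only 1 library labelled 2 dpi. Without P19 replicate 1, 2 genes passed (trnR and rrn16), and the log2 differences were 0.19 for psbA, -0.27 for trnI, 0.20 for petB and -0.22 for rpoC2. P19 then has no library labelled 2 dpi, so these values come from the 2 editor groups alone. Replicate 1 deviated in rrn16 by -1.08 with pGWB2 and -0.82 with pMDC32, but by 0.79 in P19. For trnR the deviations were -1.04, -0.91 and -0.24.

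**Figure D4:**
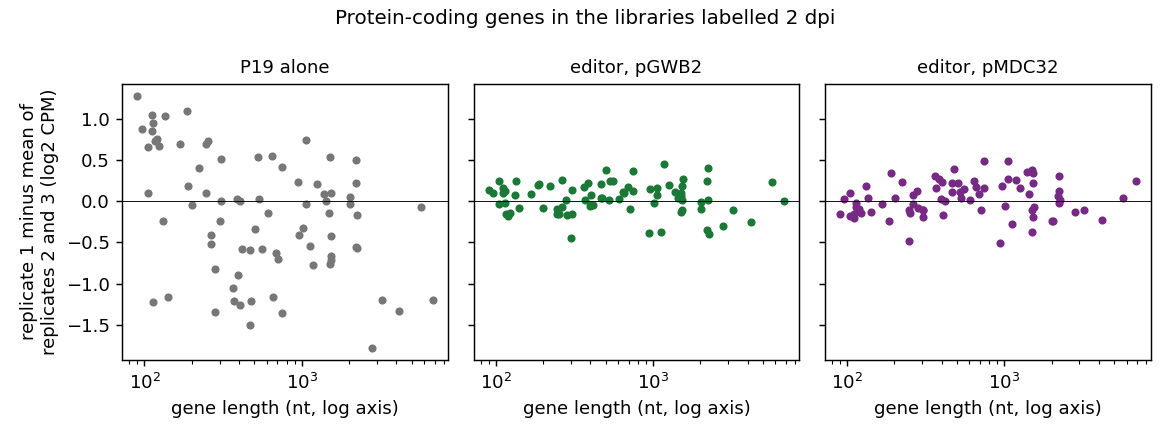
Deviation of replicate 1 from the mean of replicates 2 and 3 (log2 CPM) against gene length (nt, log axis) for 79 protein-coding genes in each group, 1 point per gene. The points spread with an SD of 0.736 in P19 leaves, 0.189 with pGWB2 and 0.21 with pMDC32.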

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

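All tests in this part were chosen only after the results were seen, except the counts of other splits of the samples for the planned comparisons and the scan of neighbouring gene pairs. An added test of whether the editor's effect differed between labelled days called 43 plastid genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (25 up, 18 down, smallest adjusted p = 0.00502), which met the rule for a difference between groups. Among named genes the log2 effect at 2 dpi minus that at 3 dpi was 1.57 for rpl22, 1.42 for rps19, 0.80 for rps7, 0.69 for rpl23 and -0.57 for psbA. At 2 dpi P19 has 1 library only, replicate 1. Of the 27 ways to take 1 library per group as the early one, 2 gave as many genes (real 43, highest other 49), so chance is not excluded. The 9 ways with P19 replicate 1 as the early control gave 18 to 49 genes and the other 18 ways 0 to 3, which points to that library, and a day effect in P19 leaves alone cannot be separated from it.

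The first pattern is P19 replicate 1 itself, at -5.95 on a first principal component on which the other libraries lie between -0.54 and 2.64. If the labelled day acted alike in every group, its deviation should match those of the other 2 dpi libraries, but the mean correlation across genes was -0.0546, while those of the editor groups correlated with each other at 0.719. Lane 8 is also argued against, since editor libraries of lane 8 lay 0.806 above those of lane 4 on that component, against its own shift of -7.17. Gene length was tested in more than 1 way, and the first test, a Spearman correlation of -0.398 (95% bootstrap interval -0.605 to -0.165), left it undecided. A second length test was added after that outcome was known: a linear term in log2 length left an SD of 0.674 of 0.736, with 0.208 at most in the other 2 dpi libraries. This argues against a linear length trend as the whole cause, but a linear term cannot exclude a relation of another shape. Such a relation, RNA quality, the lengths of whole transcripts and a day effect in P19 leaves alone stay open.

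The second pattern is petL in the pMDC32 libraries, where its ratio to its neighbour petG was 0.617 ± 0.0279 (SD, n = 3) against 0.811 ± 0.0358 in the other 6 libraries. The difference of -0.194 within libraries (exact permutation p = 0.0119, the smallest it can give, on a gene chosen for its difference) argues against whole-library normalization. Lane 8 alone is argued against by the ratio of 0.79 in P19 replicate 1 of lane 8 and of 0.594 in pMDC32 replicate 3 of lane 5, and the amount of editor transcript by the pGWB2 libraries with more of it than pMDC32 replicate 1, whose mean ratio was 0.16 higher. Among 50 neighbouring pairs the difference ranked 2 by size and 1 by size over spread, and the 1 other pair that separated the groups, petG and psaJ, shares petG, but the rank by size left a chance pick among pairs undecided. Vector, plant batch and an effect of lanes 8 and 5 alike, opposed by P19 replicate 1 alone, stay open, and a vector-dependent petL level is a hypothesis.

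For the planned counts of plastid genes, each real value was 0 and the highest of the other splits 0. As many genes came from 10 of 10 splits in each comparison of a pair of groups, 84 of 84 for both vectors and 27 of 27 for the labelled day. With a real value of 0 every split must give as many, so these splits decide nothing about adjusted counts. Genes with an unadjusted p under 0.05 by edgeR's quasi-likelihood test numbered 6 (pGWB2), 6 (pMDC32), 1 (between vectors), 16 (both vectors) and 12 (day). The highest other splits gave 18, 32, 5, 36 and 25, so none of these counts stood above the other splits. In 38 series of the 6 editor libraries no library stood out by Dixon's test.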

How the results depend on the processing

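Settings with the sequencing lane, with lane 4 alone, with psbA, rps12, tRNA, rRNA and transgene rows left out, and gene lists and the overlap of the vectors with libraries left out were chosen after seeing the data. The count of 0 plastid genes was kept in 23 of 25 alternatives for pGWB2, 20 of 24 for pMDC32, 21 of 24 between vectors, 22 of 24 for both vectors and 16 of 20 for the labelled day. DESeq2 gave 1, 1, 3 and 2 genes (pGWB2, pMDC32, both vectors and day), total counts 2 for the day, and a fit of only the groups compared 1 between vectors. The lane as covariate gave 49 for pMDC32, 40 between vectors and 3 for the day. Within lanes, pMDC32 then meets P19 only in replicate 1, and the vectors meet in no lane, so both the 49 and the 40 rest on that library. The reduced rows without P19 replicate 1 gave 5 for pGWB2, 5 for pMDC32, 5 for both and 1 between vectors, and without P19 replicate 2 they gave 1 for pMDC32 (petL). Leaving out 1 library gave 0 to 2 for the day (2 without P19 replicate 1, the only P19 library labelled 2 dpi) and 0 elsewhere. The low-count filter removed no row, so it tests nothing.

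Gene lists called by camera moved more. With an estimated correlation 0 passed in pGWB2, pMDC32 and both vectors. Without rRNA and tRNA rows 0 passed for pGWB2 and 2 for pMDC32, and size factors of DESeq2 gave 2 for pMDC32. Leaving out 1 library gave 1 to 4 for pGWB2, 0 to 4 for pMDC32, 0 to 1 between vectors and 1 to 4 for both. P19 replicate 1 gave the lows of 1, 0 and 1, and without P19 replicate 3 pMDC32 and both vectors had 1 each. Replicate numbers did not pair the libraries across all groups: correlations of deviations ran from -0.53 to 0.72, with 4 of 9 over 0.1. Of the 9 libraries, 3 correlated best with their own number. The highest value, 0.72, belonged to replicate 1 of pGWB2 and of pMDC32, both labelled 2 dpi, so a link between those 2 libraries is not excluded. With the replicate number as a block the gene counts stayed 0, and lists were 4 for pGWB2, 2 for pMDC32, 0 between vectors and 3 for both.

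Signs of gene values turned in 58 of 1786 alternatives, none of them past the threshold, and the cause was not tested. For pGWB2, libraries labelled 3 dpi alone gave rps19 -0.024 and rpl22 -0.10. The lane covariate and lane 4 alone gave rpl2 -0.056, rpl23 -0.053, rps19 -0.034 and rpl22 -0.10, and the reduced rows without P19 replicate 1 gave rpl2 -0.078, rpl23 -0.075, rps19 -0.057 and rpl22 -0.12. For pMDC32, total counts gave rps12 0.0022 and the reduced rows without P19 replicate 1 rpl23 -0.057. Between vectors the lane gave rrn16 -0.36. For both vectors, total counts gave accD 0.065 and clpP1 0.14. For rpoC1, limma-voom gave 0.053, the block 0.021, the lane 0.066, and reduced rows without P19 replicate 2 gave 0.36, with ndhB -0.0053. Libraries labelled 3 dpi alone gave rpl22 -0.015, rpoA -0.0032, clpP1 0.035, psaI 0.062, petG 0.070, rpoB -0.12, rpl32 0.0029, psbE 0.10 and rrn23 0.099. Reduced rows gave rpoA -0.015, and without P19 replicate 1 they gave rpl2 -0.017, rpl23 -0.066, rpl22 -0.054, rpoA -0.080, petG 0.013, rpoB -0.22 and rpl16 -0.034. Leaving out 1 library gave, for pGWB2, rpl2 -0.031 to 0.35, rpl23 -0.028 to 0.36, rps19 -0.010 to 0.64 and rpl22 -0.078 to 0.61, and between vectors rrn4.5 -1.05 to 0.13 and rpl2 -0.11 to 0.27. For both vectors it gave rpoA -0.010 to 0.22, clpP1 -0.088 to 0.056, psaI -0.50 to 0.071, petG -0.55 to 0.085, rpoB -0.15 to 0.44, rpl32 -0.41 to 0.020, psbE -0.44 to 0.059, accD -0.17 to 0.089 and rpoC1 -0.50 to 0.45. Of count shares it gave rRNA -0.0118 to 0.0056 points (pMDC32), tRNA -0.0394 to 0.584 (pGWB2) and psbA -2.7 to 0.191 (between vectors). At 32457135 or more counted reads, replicates differed beyond sampling noise (chi-square per degree of freedom 1359 or more), and depth itself was not varied.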

Other observations

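All tests and settings in this part were chosen only after the data were seen. With psbA, rps12, tRNA, rRNA and transgene rows and P19 replicate 1 left out, 5 genes were lower with the editor from both vectors than in P19 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. They were ndhC, ndhK and ndhJ of the NDH complex (log2 -0.59, -0.66 and -0.60), rps16 (-0.62) and rpoC1 of the RNA polymerase (-0.56), with adjusted p-values of 0.0207 to 0.0227. The library left out held all 5 below the other P19 libraries (log2 deviations -1.06, -1.35, -1.22, -0.55 and -1.78), so its removal lowered these differences. With all libraries and rows they ran from -0.55 (rps16) to -0.12 (rpoC1) with pGWB2 and from -0.33 to -0.17 (same genes) with pMDC32. The genes ndhJ, ndhK and ndhC are neighbours on the same strand and may not be separate results. The calls rest on 2 P19 libraries. Over the 24 alternatives of this comparison the smallest adjusted p ran from 0.000345 to 0.416, so these values are a lead and not a finding.

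Protein-coding genes of P19 replicate 1 spread far from the other P19 libraries. The 14 genes under 150 nt had a median log2 deviation of 0.74, the 38 of 150 to 1000 nt one of -0.29 and the 27 over 1000 nt one of -0.16, so it did not fall steadily with length.

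A hypothesis was that rpl2 transcripts follow the editor transcript across the 6 editor libraries. The editor transcript itself split these libraries by labelled day, with 1221 and 2599 CPM at 2 dpi and 4236 to 9675 CPM at 3 dpi, so no pooled correlation is used (its exact permutation p was 0.332). With the labelled day as covariate the slope of rpl2 on the editor transcript (both log2) was 0.25 (SE 0.23, n = 6, exact permutation within days p = 0.375, adjusted 0.375 over 2 relations), and that of the log2 ratio of rpl2 to rpl23 was 0.15 (SE 0.12, n = 6, exact permutation within days p = 0.229, adjusted 0.375), so the data do not decide. The ratio of rpl2 to rpl23, which needs no normalization, was 3.86 ± 0.395 with the editor (SD, n = 6) and 3.8 ± 0.112 in P19 (n = 3, exact permutation p = 0.798), with 4.6 in pMDC32 replicate 2.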
